A study of Mus musculus with 20 samples.

How the data were processed

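RNA from 20 individual pairs of XY gonads was profiled on Agilent arrays with 2 colours, 5 pairs each from C57BL/6J, 129S1/SvImJ, (B6x129S1)F1 and (129S1xB6)F1. Per the labels, gonads were taken at embryonic day 11.5 (17 to 21 tail somites), separated from the mesonephroi, and 200 to 450 ng of RNA from 1 pair was amplified per array. Gonad RNA carried Cy5 on every array, without dye swaps. The Cy3 channel held the same reference pool throughout, made from 4 pairs of XY gonads, 3 pairs of XX gonads, 4 XY and 2 XX whole embryos of a Sox9-ECFP (C57BL/6J) by CD-1 cross. Samples came from several litters per group. The letters in the sample names, 10 in all with 2 or 3 per group, were treated as a possible litter label, which the labels do not state. In C57BL/6J, arrays H1 to H4 share 1 letter and only K2 carries another.

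The values analysed were spot intensity per channel, per the file headers written by Agilent Feature Extraction 9.1.3.1, as mean signals with the median local background. The authors also deposited processed intensity columns with spatial detrending and LOWESS dye normalization, and a table of log2 ratios of Cy5 over Cy3, which were used as alternatives only. The deposited log2 ratios correlated with the ratios of the scanner files at r = 0.984 to 0.999 per array, across spots. Each array had 45018 spots, of which 43379 were gene probes. These 41174 different probes were named from their accession (22951), symbol (6659), synonym (3109) or the name given in the file (8455), which gave 27670 genes or names. The gene table of assembly GRCm38.p6 gave current symbols, X or Y linkage and neighbouring genes. The sequences of the probes were not analysed here.

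Signals were background-corrected with normexp (offset 50) and normalised by loess within each array in limma 3.58.1 (R 4.3.3, data.table version 1.17.8), with control spots at weight 0. The brightest probe on average stood for each gene. A gene was tested if its probe was well above background in Cy5 on at least 4 of the 5 arrays of at least 1 group, which left 23846 genes. The share of gene probes well above background ran from 78.4% to 88.3% per array. Median net Cy5 signal per group was 160 ± 29.8 (SD) in C57BL/6J, 192 ± 13.0 in 129S1/SvImJ, 126 ± 24.3 in (B6x129S1)F1 and 147 ± 54.5 in (129S1xB6)F1. The number of arrays limits the precision.

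A linear model with the 4 groups was fitted to all 20 arrays with moderated statistics (eBayes; 16 residual and 2.52 prior degrees of freedom), and p was adjusted by Benjamini-Hochberg over the genes tested, separately per comparison. A gene was called at an adjusted p under 0.05. The comparisons were C57BL/6J minus 129S1/SvImJ, (B6x129S1)F1 minus (129S1xB6)F1, the mean of the F1 groups minus each strain and minus the mean of the strains (mid-parent), and an F test for any difference among the groups. The F1 comparisons share arrays with each other and, for the single strains, with the strain comparison. The median standard error was 0.113 for the strain difference, 0.0977 for F1 minus a strain and 0.0797 for F1 minus mid-parent. The position of the F1 was F1 minus mid-parent divided by the strain difference over 2. Fisher's exact test, two-sided, compared X-linked with autosomal genes.

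The comparisons, the rule for naming genes, 18 gene lists with 278 entries (275 different genes) and most alternatives were chosen before the data were examined. The lists covered the male and female pathways, the bipotential gonad, germ cells, endothelial, erythroid, macrophage, mesonephros, steroidogenic and interstitial cells, the cell cycle, immediate early genes, hypoxia, FGF and WNT targets, imprinted and Y-linked genes, and label checks. They were tested with camera at a preset correlation of 0.01 between genes over 23781 genes without missing values, adjusted over the lists within a comparison, with an estimated correlation and fry as alternatives. The label checks, with 4 genes, were too few for camera. List means per array were also compared between groups by two-sided exact permutation tests. These tests take arrays as independent, and their intervals cover the spread between arrays only. Named genes were the 10 largest called differences in each direction between the strains whose arrays did not overlap, the 5 largest in each direction in every other comparison, members of the male and female lists, up to 4 members of each other list with the smallest p, and the label checks. Clone names and names that were accessions only were passed over (4 higher and 9 lower in C57BL/6J among the strain genes).

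The arrays came on 5 slides scanned on 4 days. Slide 1 held only strain arrays, slide 5 only F1 arrays, and slides 2 to 4 each held all 4 groups. Mean Cy5 net signal per slide was 187, 171, 149, 178 and 95.5 for slides 1 to 5. Slide was therefore fitted as a block and the lists were recomputed within slides. Other alternatives were an offset of 16 or no background subtraction, the processed signals, the deposited log2 ratios, Cy5 alone, quantile normalisation between arrays, no filter or a filter on all 20 arrays, the mean of all probes, a 1.5-fold minimum, only the arrays compared, scan day as a block, the letter as a random block or averaged, array weights, a trended robust fit, and leaving out each array. Fits without slide 5 and on slides 2 to 4 only were added after the data were seen.

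The procedure was tested on simulated data with 200 changed genes among 23846, in which 165 genes were called, 12 of them unchanged, and none with the wrong sign. A list shifted in the reciprocal comparison was found (adjusted p = 1.9e-13 by camera), with 0 of 16 other lists called. The simulated noise was independent between genes, whereas the estimated correlation in the data was, for example, 0.32 in the male list. The simulation therefore does not test false list calls among correlated genes. Genes simulated midway had a median position of -0.0099. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.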

Results

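Gene expression was compared in single pairs of XY gonads from embryos of day 11.5, the stage at which the gonad of the mouse commits to the testis or ovary pathway. C57BL/6J and 129S1/SvImJ are inbred strains, and the series asks what in the C57BL/6J gonad goes with its known liability to XY sex reversal. The reciprocal hybrids (B6x129S1)F1 and (129S1xB6)F1 were profiled beside them, with 5 gonad pairs per group. Differences are log2 differences of the gonad signal over a common reference pool, given with the standard error (SE) of the limma fit over all 20 arrays. Group means carry the standard deviation (SD) over 5 arrays, and the number of arrays limits their precision.

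The largest differences between the strains lay mostly outside the known sex pathways. Kctd14, whose product has the tetramerisation domain of potassium channels, was 15.0-fold higher in C57BL/6J than in 129S1/SvImJ (log2 difference 3.90 ± 0.20, adjusted p = 4.5e-10). Ptprg, a receptor tyrosine phosphatase, was 15.3-fold higher (3.94 ± 0.22, adjusted p = 1.1e-09), although the other detected probe of the gene showed a difference of 0.71. In the opposite direction Cox7c, a subunit of cytochrome c oxidase, was 7.04-fold lower in C57BL/6J (-2.82 ± 0.18, adjusted p = 5.3e-09). Of 23846 genes tested 989 differed at an adjusted p under 0.05, with 590 higher and 399 lower in C57BL/6J, and among them 139 were at least 2-fold higher and 102 at least 2-fold lower.

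The other genes of the largest higher expression in C57BL/6J had varied functions. Trim12a, from a family of tripartite motif proteins that includes antiviral factors, was 13.0-fold higher (3.70 ± 0.26, other probe 1.49), and its probe was well above background on only 3 of the 129S1/SvImJ arrays, so the size of its fold there is uncertain. Fkbp9, a peptidyl-prolyl isomerase of the endoplasmic reticulum, was 7.09-fold higher (2.83 ± 0.23). Rec8, the meiotic cohesin subunit, was 6.49-fold higher (2.70 ± 0.22, other probe 1.13). Gng13, a G protein gamma subunit that was also on the female pathway list, was 5.96-fold higher (2.58 ± 0.22). Pop4, a protein subunit of ribonuclease P, was 5.51-fold higher (2.46 ± 0.10, other probe 1.09). The X-linked histone gene H2ap was 5.06-fold higher (2.34 ± 0.33). Prim2, the large subunit of DNA primase, was 8.32-fold higher by its brightest probe (3.06 ± 0.22), while its other probe showed -0.12. Rrp7a, which acts in ribosomal RNA processing, was 5.76-fold higher by its brightest probe (2.53 ± 0.14), while its other probe showed 0.04. Adjusted p over these genes ran from 1.7e-11 for Pop4 to 1.4e-04 for H2ap.

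Genes with lower expression in C57BL/6J included several with more than a single probe in the same direction. Ppp4r4, a regulatory subunit of a serine/threonine phosphatase, was 4.96-fold lower (-2.31 ± 0.32, other probe -2.00). Myo6, an unconventional myosin that moves toward the minus end of actin, was 4.18-fold lower (-2.06 ± 0.20), with its other probes between -1.64 and -1.04. The predicted gene Gm10413 was 4.89-fold lower (-2.29 ± 0.22), with its 4 other probes between -2.12 and -0.31, and the predicted gene Gm3696 was 4.78-fold lower (-2.26 ± 0.12). Gbp2b, an interferon-inducible guanylate-binding protein, was 4.09-fold lower (-2.03 ± 0.38). Rbm45, an RNA-binding protein, was 3.95-fold lower (-1.98 ± 0.23), Cbr1, a carbonyl reductase, 3.76-fold lower (-1.91 ± 0.10), and Tescl, a relative of the calcium-binding protein tescalcin, 3.55-fold lower (-1.83 ± 0.21). Ywhaz, an adaptor of the 14-3-3 family, was 3.74-fold lower by its brightest probe (-1.90 ± 0.20), while its other probes showed -0.21 and 0.09. Adjusted p over these genes ran from 6.1e-10 for Gm3696 and Cbr1 to 0.0026 for Gbp2b. Every array of one strain lay above every array of the other for 1010 of the 23846 genes tested, a separation that chance gives for 0.794% of genes, and 734 of these 1010 were called.

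**Figure D1:**
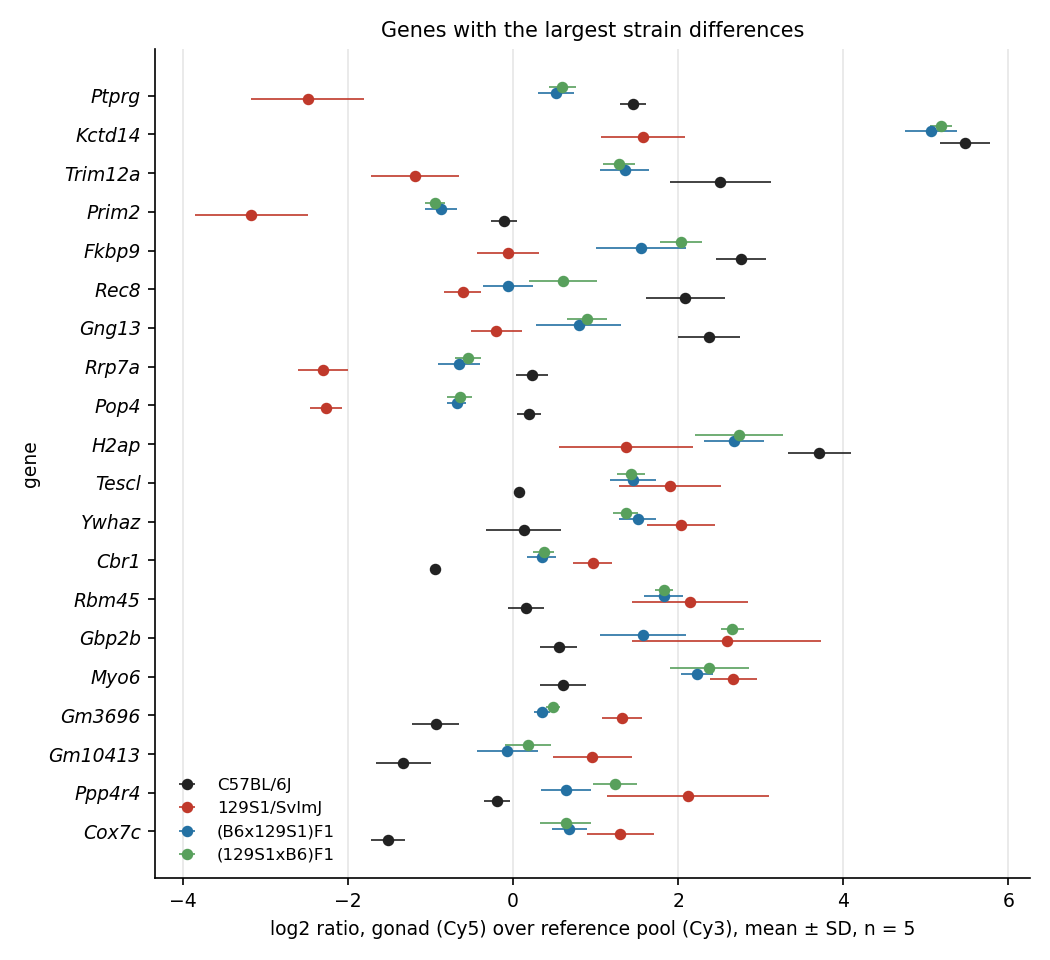
Mean log2 ratio of gonad over reference pool for the 20 genes with the largest differences between the strains, by group. Points are means and bars SD over 5 arrays; Kctd14 averaged 5.48 in C57BL/6J and 1.57 in 129S1/SvImJ, with both F1 groups near C57BL/6J.

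Genes of the female pathway were higher in C57BL/6J XY gonads, and those of the male pathway showed no shared shift. Fst, which encodes the activin antagonist follistatin and marks the early ovary, was 2.01-fold higher (1.00 ± 0.17, adjusted p = 0.0011). Lef1, a transcription factor that acts with beta-catenin, was 1.60-fold higher (0.68 ± 0.16, adjusted p = 0.014), with 0.20 at its other probe. Over the 14 tested genes of the female list the median difference was 0.46, with 12 genes above 0 (adjusted p = 1.1e-05 by camera). The call held, at adjusted p = 0.021, with an estimated correlation between genes. Gng13, Fst and Lef1 were called among all genes tested, and 6 of the 14 when adjusted over the list alone. Wnt4 (0.64 ± 0.25), Rspo1 (0.62 ± 0.20) and Bmp2 (0.54 ± 0.17), signals of the ovarian program, and Nr0b1 (0.82 ± 0.37), a dosage-sensitive nuclear receptor, did not pass over all genes, with adjusted p from 0.098 for Bmp2 to 0.34 for Nr0b1. Foxl2, a later ovarian regulator, differed by 0.00 ± 0.08. Per array, the list mean lay 0.56 higher in C57BL/6J (95% interval 0.32 to 0.78; exact permutation test, two-sided, p = 0.00794, the smallest that 5 against 5 arrays can give; adjusted p = 0.048 over the lists). The exact test takes arrays as independent, while C57BL/6J arrays H1 to H4 share 1 letter, a possible litter. With slide as a block the median stayed at 0.46, which the balance of the strains on each slide fixes. Within slides 1 to 4 it was 0.48, 0.82, 0.55 and 0.34.

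Targets of canonical WNT signalling moved the same way. Sp5, a zinc finger gene switched on directly by beta-catenin, was 2.42-fold higher in C57BL/6J (1.27 ± 0.25, adjusted p = 0.0039). Rnf43, a membrane ubiquitin ligase that dampens WNT signalling, was 1.64-fold higher (0.71 ± 0.18, adjusted p = 0.028), and Ccnd1, the cyclin that drives entry into the cell cycle, 1.32-fold higher (0.40 ± 0.11, adjusted p = 0.039), though Ccnd1 lost its call in 8 of 16 alternatives. Of 10 fits that left out 1 array, Rnf43 lost its call in 5 and Ccnd1 in 7. All 12 tested genes of the list lay above 0, with a median of 0.29 (adjusted p = 7.2e-05 by camera, and adjusted p = 0.012 with an estimated correlation). With Lef1, 4 of the 12 were called among all genes and 5 when adjusted over the list alone. Per array, the list mean was 0.43 higher in C57BL/6J (95% interval 0.23 to 0.63; exact permutation p = 0.00794, again the smallest possible; adjusted p = 0.048). The label checks were again among the lists of this adjustment and lower the adjusted p. The median with slide as a block was called as well (adjusted p = 2.1e-04), and within slides 1 to 4 the medians were 0.42, 0.23, 0.53 and 0.50. Axin2 and Lef1 were on both this list and the female list.

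Male pathway genes went in both directions between the strains. Gadd45g, a stress-response gene needed for timely activation of Sry, was 1.48-fold higher in C57BL/6J (0.56 ± 0.13, adjusted p = 0.015), the only member of the list called among all genes or adjusted over the list alone. Sox9, the transcription factor that commits cells to the Sertoli fate, averaged 0.63 ± 0.48 (SD) in C57BL/6J and -0.30 ± 0.96 in 129S1/SvImJ, a difference of 0.94 ± 0.38 that did not pass (adjusted p = 0.25). Sry, the switch gene on the Y chromosome, differed by 0.01 ± 0.07, with its probe well above background on 3 or 4 arrays of each group. Fgf9, a growth factor that sustains Sox9, differed by 0.00 ± 0.32, Dmrt1 by 0.62 ± 0.21 (adjusted p = 0.12) and Amh, the hormone that removes the female duct, by -0.22 ± 0.18 (adjusted p = 0.74). Of 22 genes 12 lay above 0 and 10 below, with a median of 0.01 (camera adjusted p = 0.54). The per-array list mean differed by 0.06, with a 95% interval from -0.71 to 0.80 (exact permutation p = 0.85), so a shift of the size seen in the female list was not excluded.

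**Figure D2:**
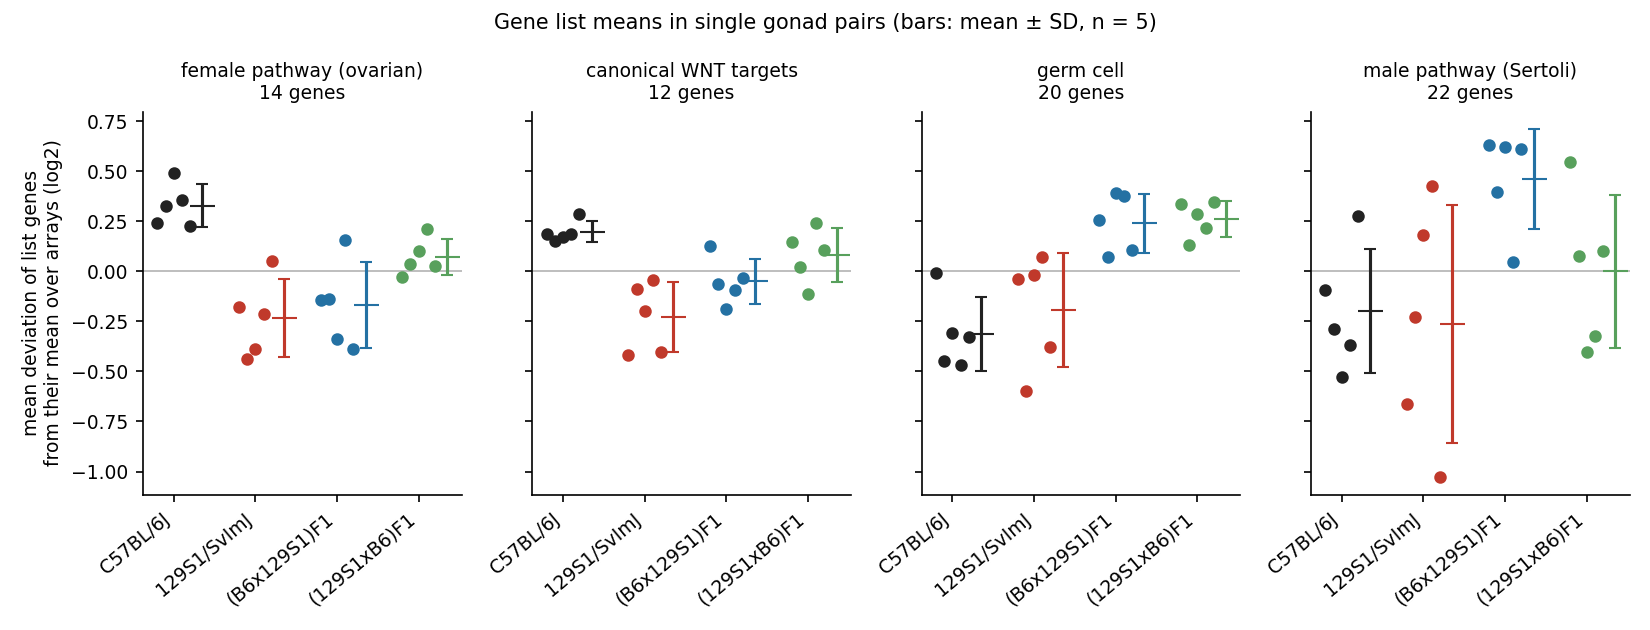
Mean log2 deviation of the genes of 4 lists from their mean over all arrays, for each gonad pair, with group mean ± SD over 5 arrays. The female list averaged 0.33 in C57BL/6J and -0.23 in 129S1/SvImJ, and the germ cell list 0.24 and 0.26 in the F1 groups against -0.31 and -0.19 in the strains.

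Among genes of other cell types and processes, single members differed between the strains while the lists as a whole were not called by camera. Emx2, a homeobox gene required for the gonad to form, was 2.08-fold higher in C57BL/6J (1.05 ± 0.25, adjusted p = 0.015), and Cited2, a co-activator upstream of Sry, showed 0.58 ± 0.17 (adjusted p = 0.053). Their list of bipotential gonad genes had a median of 0.11 over 18 genes (adjusted p = 0.23), with 1 gene called over all genes and 4 adjusted over the list alone. Lhx1, a regulator of the nephric duct, was 1.45-fold lower in C57BL/6J (-0.54 ± 0.12, adjusted p = 0.015), and the mesonephros and duct list had a median of 0.04 over 13 genes (adjusted p = 0.42; 3 called adjusted over the list alone). Hsd3b1, an enzyme of steroid synthesis, was 2.08-fold lower (-1.06 ± 0.23, adjusted p = 0.0089), in a steroidogenic list with a median of -0.12 over 11 genes (adjusted p = 0.083). Ndrg1, a hypoxia target, was 1.61-fold higher (0.69 ± 0.14, adjusted p = 0.0065), in a hypoxia and glycolysis list with a median of 0.13 over 13 genes (adjusted p = 0.083). Mcm6, part of the replicative helicase, was 1.42-fold higher (0.51 ± 0.12, adjusted p = 0.017), while the 21 cell cycle genes had a median of 0.02, a mean of -0.01 and a camera direction below 0 (adjusted p = 0.77). Inpp5f, an imprinted phosphatase gene, was 1.63-fold lower (-0.71 ± 0.16, adjusted p = 0.014), in an imprinted list with a median of -0.03 over 34 genes (adjusted p = 0.27).

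Apart from the label checks, the remaining lists had no member called between the strains. Germ cell genes had a median of -0.13 over 20 genes (adjusted p = 0.23), endothelial genes -0.14 over 14 (adjusted p = 0.12), erythroid genes 0.17 over 13 (adjusted p = 0.42) and macrophage genes 0.06 over 14 (adjusted p = 0.54). Interstitial progenitor genes had a median of 0.02 over 9 genes (adjusted p = 0.91) and immediate early genes -0.04 over 16 (adjusted p = 0.77). Targets of FGF signalling had a median of 0.03 over 11 genes, with a mean of -0.06 and a camera direction below 0 (adjusted p = 0.54). Y-linked genes had a median of -0.03 over 8 genes (adjusted p = 0.61), with Kdm5d at 0.31 ± 0.12 and Uba1y at -0.75 ± 0.30, neither called. Of the 4 genes chosen to check the strain labels (median -0.44), Nnt, a mitochondrial transhydrogenase gene that carries a deletion in C57BL/6J, was 1.60-fold lower there (-0.68 ± 0.12, adjusted p = 0.0016; its 3 other probes between -0.42 and -0.04). Ren2 (-0.75 ± 0.36), Disc1 (-0.20 ± 0.07) and Xist (0.13 ± 0.09) were not called.

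Fewer X-linked than autosomal genes differed between the strains. Of 630 X-linked genes tested, 13 were called (2.06%), against 773 of 17460 autosomal genes (4.43%; odds ratio 0.455, 95% interval 0.240 to 0.789; Fisher's exact test, two-sided, p = 0.00267). X status was taken from the gene table of assembly GRCm38.p6. The call with the largest size after H2ap was Lancl3, a gene named for lanthionine synthetase, which was lower in C57BL/6J (-1.97 ± 0.34, adjusted p = 0.0014); it was chosen after its values were seen.

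No gene was called between the reciprocal crosses. They carry the same autosomal alleles but differ in the strain of their X and Y and in which parent gave each imprinted allele. By limma 0 of 23846 genes were called, with 598 at an unadjusted p under 0.05, and with slide as a block 0 and 797. Both 598 and 797 lie below the share of 0.05 of genes that chance alone gives. The spread was estimated over all 4 groups, and p may run high here, so 0 calls do not show that no gene differs. With only the arrays compared, 1 gene was called. The largest single difference in the male list was in Dhh, a hedgehog signal from Sertoli cells, 3.73-fold higher in (B6x129S1)F1 (1.90 ± 0.82, means 5.26 ± 0.95 and 3.36 ± 1.13 (SD)) but not called. Sp5 showed -1.0 ± 0.25, below 0 on each of the 4 slides with both crosses, and was the only gene called when adjusted over a list alone. The labels do not state which parent was the mother in either cross name. In simulated data of the same size, where only a gene list was shifted by log2 0.5 between the crosses, the fit called 2 genes there, while of simulated strain differences it recovered 50.6% at log2 0.5, 87.3% at log2 1 and 100% at log2 2. The simulated noise had the same spread in every group, so these rates need not hold for the real crosses.

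By gene lists, the crosses differed with the preset correlation of camera and with slide as a block, but not with an estimated correlation. Male pathway genes had a median of 0.34 toward (B6x129S1)F1, with 17 of 22 genes above 0 (adjusted p = 1.7e-04; adjusted p = 0.28 with an estimated correlation). Amh (0.43 ± 0.18), Cbln4, a secreted synaptic organiser also made by Sertoli cells (0.38 ± 0.16), and Vnn1, a pantetheinase of early Sertoli cells (0.30 ± 0.11), lay above 0 on all 4 slides that held both crosses. With slide as a block the male median stayed at 0.34, which the balance of the crosses on each slide fixes (adjusted p = 4.9e-04 by camera). Within slides 2 to 5 it was 0.74, 0.31, 0.06 and 0.36. Female pathway genes had a median of -0.30, with 12 of 14 below 0 (adjusted p = 2.2e-04; adjusted p = 0.083 with an estimated correlation), and within the slides -0.44, -0.23, -0.16 and -0.20. Among them were Axin2, a feedback inhibitor of WNT signalling (-0.41 ± 0.15), Lef1 (-0.34 ± 0.16), Msx1 (-0.36 ± 0.18) and Sprr2d (-0.67 ± 0.39). The per-array list means differed by 0.46 in the male list (95% interval -0.03 to 0.98; exact permutation p = 0.056, adjusted p = 0.39) and by -0.24 in the female list (-0.48 to 0.01; exact permutation p = 0.071).

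3 further lists were called between the crosses, again only with the preset correlation and the slide block. Y-linked genes had a median of -0.12 with all 8 below 0 (adjusted p = 0.0035; adjusted p = 0.14 with an estimated correlation), but -0.35, 0.09, 0.05 and -0.13 within slides 2 to 5. WNT targets had a median of -0.16 (adjusted p = 0.0078; adjusted p = 0.083 with an estimated correlation), and 0.28, -0.20, -0.00 and -0.23 within the slides. Bipotential gonad genes had a median of -0.09 (adjusted p = 0.035; adjusted p = 0.14 with an estimated correlation), and -0.02, -0.13, -0.16 and 0.04 within the slides. Imprinted genes were not called (median 0.01, mean -0.06, camera direction below 0, adjusted p = 0.48). At an unadjusted p under 0.01 were 8 of 630 X-linked genes (1.27%) and 59 of 17460 autosomal genes (0.338%). The X-linked share was the higher (odds ratio 3.79, 95% interval 1.56 to 8.02, Fisher's exact p = 0.00221). Chance alone gives 1%, near the X-linked share. The autosomal share lay below it, so p may run high in this comparison and 1% may be too high a yardstick.

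Against C57BL/6J, the F1 gonads were higher in germ cell genes and lower in female pathway genes. Cox7c was 4.52-fold higher in the F1 (2.18 ± 0.15, adjusted p = 1.2e-07), Myo6 3.24-fold (1.70 ± 0.17, adjusted p = 1.1e-05) and Rbm45 3.18-fold (1.67 ± 0.20, adjusted p = 1.2e-04). Zfp42, the pluripotency gene also called Rex1, was 4.17-fold higher (2.06 ± 0.28, adjusted p = 3.8e-04), and Rpl39l, a ribosomal protein gene of germ cells, 3.40-fold (1.77 ± 0.28, adjusted p = 0.0017). Rec8 was 3.53-fold lower (-1.82 ± 0.19), Gng13 2.88-fold (-1.53 ± 0.19), Trim12a 2.28-fold (-1.19 ± 0.23), Ccdc61, a centriolar coiled-coil protein, 2.08-fold (-1.05 ± 0.14) and Fst 2.06-fold (-1.04 ± 0.15). The comparison called 404 genes, 213 higher and 191 lower in the F1, with 51 and 9 of them at least 2-fold; the share higher was 52.7%, and 43.3% without background subtraction. The F1 arrays were spread over slides 2 to 5 and slide 5 held F1 arrays only; with slide as a block 258 genes were called, 167 higher and 91 lower, and 187 of them were among the 404. The count was 221 without H2 and 233 without H3, both C57BL/6J.

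Germ cell genes had a median of 0.59 above C57BL/6J, with 19 of 20 genes above 0 (adjusted p = 1.3e-14; adjusted p = 0.014 with an estimated correlation; 0.63, 0.36 and 0.77 within slides 2 to 4). Mael, which silences transposons in germ cells (0.82 ± 0.13), Dppa5a, a pluripotency RNA-binding protein (1.22 ± 0.22), Ddx4, the germ cell helicase (1.16 ± 0.26), and Tfap2c, a transcription factor of primordial germ cells (0.65 ± 0.15), were called, and 18 genes of the list when adjusted over the list alone (17 higher and 1 lower). Ddx4 and Tfap2c each lost the call in 8 of 15 fits that left out 1 array. Female pathway genes had a median of -0.33 (adjusted p = 7.8e-06; adjusted p = 0.024 with an estimated correlation; -0.47, -0.19 and -0.40 within slides 2 to 4), with Gng13 and Fst called and 8 genes adjusted over the list alone. WNT targets had a median of -0.22 (adjusted p = 0.0044; adjusted p = 0.040 with an estimated correlation; -0.24, -0.38 and -0.11 within the slides), with Sp5 called (-1.01 ± 0.22, adjusted p = 0.017). Male genes (0.41, adjusted p = 0.0044; adjusted p = 0.40 with an estimated correlation) showed 0.41, -0.03 and 0.86 within slides 2 to 4, and the 2 members called when adjusted over the list alone were both lower in the F1. Macrophage genes (-0.12, adjusted p = 0.013; adjusted p = 0.40 with an estimated correlation) showed 0.06, -0.31 and -0.41. FGF targets (0.15, adjusted p = 0.012; adjusted p = 0.23 with an estimated correlation) showed 0.23, 0.01 and 0.34 and were not called with the slide block (adjusted p = 0.11), though Etv4, an ETS factor downstream of FGF, was called (0.98 ± 0.23, adjusted p = 0.038). Of single genes of other lists, Lhx1 (0.46 ± 0.11) and Egln3, an oxygen-sensing hydroxylase (0.30 ± 0.07), were higher in the F1, Ndrg1 lower (-0.58 ± 0.12), and the Y-linked Uba1y higher (1.51 ± 0.26, adjusted p = 0.0035). Etv4 and Lhx1 each lost the call in 11 of 15 fits that left out 1 array.

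Against 129S1/SvImJ, with which the strain comparison shares its arrays, the F1 gonads were higher in several genes that were also high in C57BL/6J. Kctd14 was 11.7-fold higher (3.55 ± 0.18, adjusted p = 9.7e-10), Ptprg 8.25-fold (3.04 ± 0.19, adjusted p = 1.8e-08), Trim12a 5.69-fold (2.51 ± 0.23, with the same uncertainty), Prim2 4.80-fold by its brightest probe (2.26 ± 0.19, other probe -0.13) and Fkbp9 3.62-fold (1.86 ± 0.20). Pcdh9, a protocadherin, was 2.63-fold lower in the F1 (-1.40 ± 0.17, adjusted p = 1.3e-04), with its 4 other probes in the same direction. Ppp4r4 was 2.26-fold lower (-1.17 ± 0.28, adjusted p = 0.038; the call was lost in 11 of 15 fits that left out 1 array), Gm10413 1.87-fold (-0.90 ± 0.19), Gm3696 1.86-fold (-0.90 ± 0.11) and Wdfy1, an endosomal protein, 1.80-fold (-0.85 ± 0.11). Gng13 was higher in the F1 than in 129S1/SvImJ (1.05 ± 0.19), and Nnt lower (-0.59 ± 0.10), as was Inpp5f (-0.57 ± 0.14), which lost its call in 13 of 16 alternatives. The comparison called 319 genes, 194 higher and 125 lower, with 41 and 3 of them at least 2-fold; in the count of genes, F1 minus 129S1/SvImJ, the share higher was 60.8%, and 50.1% without background subtraction. With slide as a block 126 were called, 101 higher and 25 lower, with 94 of them among the 319, and the count was 175 without G3 and 211 without A3, both 129S1/SvImJ.

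Germ cell genes were above 129S1/SvImJ as well, with a median of 0.35 and 19 of 20 genes above 0 (adjusted p = 1.3e-07; adjusted p = 0.14 with an estimated correlation; 0.71, 0.16 and 0.64 within slides 2 to 4). Ddx4 (2.89-fold, 1.53 ± 0.26), Rhox6, a homeobox gene of the X-linked reproductive cluster (2.28-fold, 1.19 ± 0.28), and Alpl, the alkaline phosphatase that marks germ cells (0.81 ± 0.17), were called, and 10 genes when adjusted over the list alone; Rhox6 lost its call in 9 of 16 alternatives. Male pathway genes had a median of 0.40 (adjusted p = 1.5e-04; adjusted p = 0.46 with an estimated correlation), but 0.26, -0.00 and 1.39 within slides 2 to 4. WNT targets had a median of 0.23 (adjusted p = 0.036; adjusted p = 0.14 with an estimated correlation; 0.11, 0.21 and 0.09 within the slides; adjusted p = 0.23 with the slide block). Hypoxia genes had a median of 0.15 (adjusted p = 0.031; adjusted p = 0.14 with an estimated correlation; 0.25, 0.21 and 0.02 within the slides; adjusted p = 0.38 with the slide block), with Egln3 called (0.27 ± 0.07) but not in 10 of 16 alternatives.

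As a list, germ cell genes lay above the mean of the strains in the F1 gonads, while most single genes called there were not on it. Ddx4 was 2.54-fold above the mid-parent value (1.34 ± 0.21, adjusted p = 0.0084), Dppa5a 1.95-fold (0.96 ± 0.18, adjusted p = 0.024), Alpl 1.61-fold (0.69 ± 0.14, adjusted p = 0.036) and Mael 1.55-fold (0.63 ± 0.10, adjusted p = 0.0099). Over 20 germ cell genes the median was 0.45, with 19 above 0 (adjusted p = 1.8e-17; adjusted p = 0.0060 with an estimated correlation); 4 were called among all genes and 14 adjusted over the list alone. Off the list, Kctd14 was 3.03-fold above mid-parent (1.60 ± 0.14, adjusted p = 3.0e-05), and Rpl39l (2.69-fold, 1.43 ± 0.23), Tex19.1, a germ cell and placental gene (2.55-fold, 1.35 ± 0.21), and Zfp42 (2.30-fold, 1.20 ± 0.23) followed. Mid-parent is a mean of log2 values, which lies below the mean of unlogged values where the strains differ widely, as for Kctd14. The Y-linked Uba1y was 2.20-fold above (1.14 ± 0.21, adjusted p = 0.024) and Egln3 1.22-fold (0.29 ± 0.05). Below mid-parent were Minar2 (-0.48 ± 0.10, other probe 0.11) and Vsnl1, a neuronal calcium sensor (-0.17 ± 0.04, other probe 0.04), which lost their calls in 10 and 12 of 15 alternatives, as Alpl did in 8. Of 63 genes called, 59 were above and 4 below mid-parent, and 9 were at least 2-fold above. Fst (-0.54 ± 0.12), Dhh (1.70 ± 0.58), Cst9, a cystatin of Sertoli cells (1.09 ± 0.36), Dusp4 (0.53 ± 0.14) and Etv4 (0.60 ± 0.19) were not called.

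With slide as a block 9 genes were called against mid-parent, all above it, and 6 of them were among the 63. Kctd14 (1.48, adjusted p = 0.026) and Dppa5a (1.15, adjusted p = 0.027) were among these, whereas Ddx4 had an adjusted p = 0.18 and Mael 0.059. The germ cell list median was 0.55 with the block (adjusted p = 6.9e-18), and 0.60, 0.31 and 0.65 within slides 2 to 4. The count of 63 was 27 without M6 and 32 without C4, both F1 arrays, and among the strains 31 without H3, 32 without H2 and 39 without G3. Male pathway genes had a median of 0.41 above mid-parent (adjusted p = 8.0e-06; adjusted p = 0.33 with an estimated correlation), with none called among all genes and 6 adjusted over the list alone (5 higher and 1 lower); within slides 2 to 4 the medians were 0.29, -0.00 and 1.10. Macrophage genes had a median of -0.12 (adjusted p = 0.012; adjusted p = 0.40 with an estimated correlation), and 0.10, -0.21 and -0.24 within the slides. FGF targets had a median of 0.13 (adjusted p = 0.012; adjusted p = 0.33 with an estimated correlation), 0.11, 0.10 and 0.44 within the slides, and an adjusted p = 0.13 with the slide block. Female pathway genes were not called (median -0.12, adjusted p = 0.064).

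Genes that differed between the strains lay on average midway in the F1 on the log2 scale. Genes higher in either strain were pooled, so a lean toward the higher strain could cancel, which was not tested. On a scale where 1 is C57BL/6J and -1 is 129S1/SvImJ, the median position of the 989 called genes was -0.0069 (95% interval -0.045 to 0.025, from resampling genes, which are not independent), with quartiles at -0.34 and 0.30. The F1 mean of 944 genes (95.5%) lay between the strains, 16 lay beyond C57BL/6J and 29 beyond 129S1/SvImJ. Nearer to C57BL/6J were 489 genes and nearer to 129S1/SvImJ 500. Kctd14 lay close to C57BL/6J, at 5.07 ± 0.31 (SD) in (B6x129S1)F1 and 5.18 ± 0.13 in (129S1xB6)F1 against 5.48 ± 0.30 in C57BL/6J and 1.57 ± 0.51 in 129S1/SvImJ. The slope of F1 minus mid-parent on the strain difference divided by 2 was -0.0188 ± 0.0140, and taken singly the crosses had medians of -0.052 for (B6x129S1)F1 and 0.036 for (129S1xB6)F1.

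**Figure D3:**
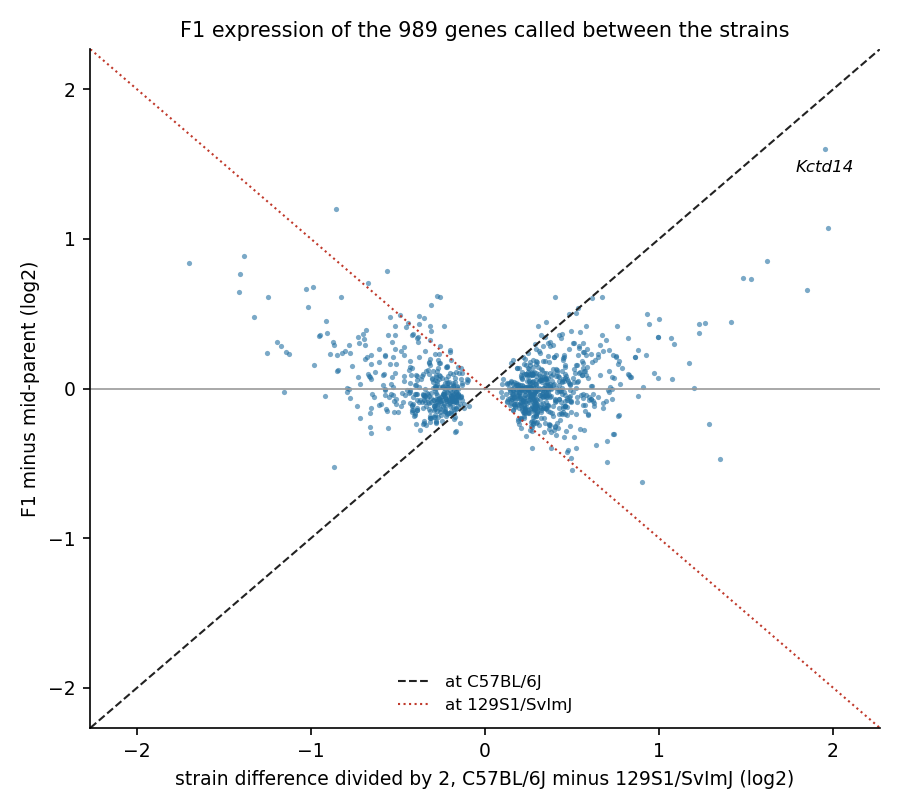
F1 minus mid-parent against the strain difference divided by 2 (log2) for the 989 genes called between the strains, a point per gene. The dashed and dotted lines mark F1 expression equal to C57BL/6J and to 129S1/SvImJ; 944 genes lay between the strains.

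Tested for any difference among the 4 groups, 683 genes were called, and 729 with slide as a block. The strains separated along the second principal component (14.7% of variance), where C57BL/6J arrays scored from 10.6 to 29.9 and 129S1/SvImJ arrays from -27.0 to -8.58, with the F1 arrays from -10.2 to 11.3. The range of pairwise correlations between arrays across genes, which are not independent replicates, was 0.792 to 0.918 in C57BL/6J, 0.768 to 0.874 in 129S1/SvImJ, 0.855 to 0.925 in (B6x129S1)F1 and 0.849 to 0.913 in (129S1xB6)F1.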

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

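The tests of probe variants, of slides (strain genes, female list, germ cell list), of other cell types, of mesonephros tissue and of an earlier stage were chosen only after the result was seen, and the tests of other splits and of the reference channel before. Single arrays lay far from the other 4 of their group in 27 of 313 sets of 5 arrays, by the gap to the nearest array relative to the range; chance alone would give 15.6. Of the 27, 20 were single genes. C57BL/6J array K2 was the distant array in 7 and 129S1/SvImJ array G3 in 5.

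In C57BL/6J, K2 stood apart from the other arrays for Prim2 (0.17 against -0.22 to -0.17), Gbp2b (0.15 against 0.63 to 0.70), Ywhaz (-0.65 against 0.18 to 0.49), Tescl (0.15 against 0.05 to 0.06) and Dusp4 (0.52 against -0.76 to -0.41), all as log2 ratios over the reference. Its list means also stood apart for FGF targets (0.094 against -0.22 to -0.16) and WNT targets (0.29 against 0.15 to 0.19). Dmrt1 was high on H2 (2.19 against 1.40 to 1.56), Tfap2c low on H4 (-0.39 against 0.04 to 0.19), and on H3 Inpp5f (-1.15 against -1.42 to -1.35) and the label check list (-0.11 against -0.24 to -0.22) were high. In 129S1/SvImJ, A4 stood apart for Trim12a (-0.25 against -1.53 to -1.31), Prim2 (-1.99 against -3.71 to -3.22) and Nr0b1 (1.69 against 3.39 to 3.87). G3 was high for Bmp2 (1.12 against 0.00 to 0.05), Emx2 (2.13 against 0.93 to 1.17), Ndrg1 (0.97 against 0.52 to 0.62), Nnt (0.93 against 0.30 to 0.46) and the hypoxia list (0.073 against -0.19 to -0.16). The macrophage list was high on A3 (0.33 against -0.13 to -0.02) and the mesonephros list on A6 (0.21 against -0.21 to -0.11).

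In (B6x129S1)F1, Uba1y was high on C4 (3.45 against 2.56 to 2.80), Tfap2c high on E1 (1.11 against 0.36 to 0.53), Dhh low on E1 (3.59 against 5.44 to 5.97), Gm10413 low on F2 (-0.72 against 0.03 to 0.21), and the macrophage list low on C4 (-0.19 against -0.09 to -0.06). In (129S1xB6)F1, Fst was low on M6 (-1.01 against -0.49 to -0.37). The reference channel, which held the same RNA on every array, was not used alone in the Results, only in the checks of this section. Fitted alone with limma, it gave 2 genes called between the strains, 69 between the F1 and 129S1/SvImJ and 28 between the F1 and mid-parent. It gave 0 between the crosses and 0 between the F1 and C57BL/6J, where 60 and 2266 genes had an unadjusted p under 0.05. That number was 393 between the strains, 5920 between the F1 and 129S1/SvImJ and 6365 between the F1 and mid-parent, of 23846 genes. Chance alone gives a share of 0.05, which the F1 comparisons with either strain and with mid-parent exceeded. As the reference RNA was the same, these differences between F1 and strain arrays are technical. How far they enter the genes called in those comparisons was not tested.

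Of the 989 genes called between the strains, 59.7% were higher in C57BL/6J (95% interval 56.5% to 62.7%, which takes genes as independent). A variant of 129S1/SvImJ under a probe lowers the signal of that probe only, unless probes overlap, which was not checked. As the whole cause it then leaves other probes of the gene without a shared direction. For 370 called genes with other detected probes, 73.2% of those 534 probes had the same sign as the called probe (95% interval 68.8% to 77.4%, from resampling genes). The share was 54.7% for genes with an unadjusted p over 0.5, which argues against variants under single probes as the whole cause. Their differences had a median of 0.238 times that of the called probe, and only 33.7% were at least 0.5 times as large. Genes higher in 129S1/SvImJ showed much the same (0.244 times, 31.9%) as genes higher in C57BL/6J (0.227 times, 35.1%). Such variants cannot give the former if the probes follow C57BL/6J sequence, which was not checked. Under that premise the small ratios do not point to variants. Variants may still stand behind part of the calls higher in C57BL/6J, such as Prim2 and Rrp7a, and the share of 59.7% leaves room for that. Under the same premise Ywhaz, lower in C57BL/6J, is not among these. With slide as a block 1208 genes were called, 948 of them among the 989. The strains are balanced on each slide, so a shift shared by the arrays of a slide cannot be the whole cause. The same balance fixes the strain differences with the block, so the count of 1208 is no test of slides. Chance among independent arrays is excluded too (989 genes, highest other split 156, 1 of 100 as large).

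Germ cell genes lay above mid-parent in the F1 by a median of 0.45. Among the other assignments of the 20 arrays the median farthest from 0, in either direction, had a size of 0.35. Chance among independent arrays can therefore be excluded (1 of 100). Slide 5, with F1 arrays only, is excluded as the whole cause by a median of 0.42 without it. The Cy3 channel alone argues against a lower reference signal, with a list median of 0.017 (95% interval -0.04 to 0.12). This interval and the next came from resampling genes, which are not independent, and leave out the spread between arrays. A smaller share of the main cells would raise other minor cell types alike, but 41 endothelial, macrophage and mesonephros genes had a median of -0.064 (95% interval -0.12 to 0.01). A larger number of germ cells in the hybrids, or more RNA per germ cell, may therefore be behind the difference, as a hypothesis that these data cannot decide; averaging arrays that share a letter left the median at 0.41, and exact age within the range of tail somites was not tested.

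Female pathway genes were higher in C57BL/6J by a median of 0.46, and 3 of 100 splits, the real one included, gave a median as large (highest other 0.62). This argues against chance among independent arrays but does not exclude it. For the median of the WNT targets alone chance stays open (0.29, 9 of 100, highest other 0.38), although their list means separated the strains fully (exact permutation p = 0.00794 over all 252 splits). The larger splits of the female list moved G3 to the side of C57BL/6J and so put both strain arrays of slide 4 on one side. In the real groups the strains are balanced on each slide, which fixes the median with slide as a block at 0.46. Within slides the lowest median was 0.34, so slides are excluded as the whole cause. Mesonephros tissue carried along with C57BL/6J gonads was taken to raise the mesonephros and duct epithelium list by about as much. The list median of 0.036 argues against such tissue as the whole cause, but parts of the mesonephros without these genes are not covered. Such tissue cannot be told apart as part of the cause, since the 95% interval of that median reaches 0.28. That interval came from resampling genes and leaves out the spread between arrays. An earlier stage of the C57BL/6J gonads could also give higher female genes and lower male genes, and it cannot be told apart because the male list means differed by 0.062 with an interval wider than that; the strain itself stays open as the biological explanation.

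For the other comparisons, the real groups gave more called genes than every other assignment drawn, so chance among independent arrays can be excluded: 404 genes between the F1 and C57BL/6J (highest other 3; 1 of 100), 319 between the F1 and 129S1/SvImJ (highest other 63; 1 of 100), 63 against mid-parent (highest other 2; 1 of 100) and 683 among the 4 groups (highest other 16; 1 of 100). These assignments, like the splits above, moved single arrays, so they do not cover litter or slide effects. The assignment with 63 genes for the F1 and 129S1/SvImJ kept slides 1 and 5 on the sides they really had; with slide as a block the real groups gave 258, 126 and 9 genes for the F1 against C57BL/6J, 129S1/SvImJ and mid-parent, and 2 against mid-parent without slide 5. With a mean per letter, a possible litter, 318 genes were called between the strains, 12 between the F1 and C57BL/6J, 68 between the F1 and 129S1/SvImJ, 0 against mid-parent by limma and 126 among the groups. Between the crosses all 100 splits gave at least the 0 genes of the real split, and the highest gave 1. The median of 0.41 for male genes against mid-parent had 3 of 100 as large (highest 0.53), but it was not called with an estimated correlation (adjusted p = 0.33), so chance stays open. One of these put all 4 arrays of slide 1 on one side, and within slides 2 to 4 the medians were 0.29, -0.00 and 1.10. Between the crosses, chance cannot be excluded for male genes (0.34, 6 of 100, highest 0.46). For female genes 2 of 100 medians were as large (-0.30, highest 0.33), but the exact permutation test of the list means over all 252 splits gave p = 0.071, so chance stays open there too. One split as large for male genes (0.40) set the 4 arrays of slide 5 and L4 against the others. It gave 1945 genes at an unadjusted p under 0.05, where the real split gave 598, so slide 5 marks a structure among the F1 arrays. In the real split the crosses are balanced on each slide, which fixes the male median with slide as a block at 0.34. Within slides 2 to 5 it was 0.74, 0.31, 0.06 and 0.36.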

How the results depend on the processing

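Fits without slide 5 and on slides 2 to 4 alone were chosen after the data were seen. None of the 82 called results for named genes (of 115) and none of the called lists reversed its direction under the alternatives, although some lists changed sign within single slides, and uncalled genes near 0 such as Sry, Fgf9 and Foxl2 took either sign. The uncalled F1 position and slope crossed 0, and the share of higher genes in F1 minus C57BL/6J passed from 52.7% to 43.3% without background subtraction and 49.5% with array weights. The strain count ran from 305 to 1281 over the alternatives, the reciprocal count from 0 to 2, F1 minus C57BL/6J from 12 to 1004, F1 minus 129S1/SvImJ from 38 to 409, F1 minus mid-parent from 0 to 93 and any difference from 126 to 872. The female list stayed higher in C57BL/6J in all 19 alternatives (medians 0.26 to 0.57, adjusted p from 2.9e-07 to 0.021), the WNT targets likewise (0.12 to 0.56, 1.2e-05 to 0.012), and germ cell genes stayed above mid-parent in all 18 (0.20 to 0.56, 1.5e-19 to 0.0060). The median F1 position ran from -0.094 to 0.012, its slope from -0.065 to 0.0059, and the odds ratio of X-linked calls from 0.231 to 0.616 (p from 6.4e-04 to 0.019). Quantile normalisation left the log ratios as they were. Of the 115 results 82 were called, and 27 of these in every alternative and without each array; 55 lost the call in at least 1 alternative and 23 without some array, while 7 of 33 not called gained it in some alternative. Signal over background sets which genes can be tested and limits the dimmest ones.

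Counts that moved by more than 1.5 times, or passed from 0, were as follows, and where the alternative does not itself remove arrays or genes the cause was not tested. With a 1.5-fold minimum, which removes small differences, 570 genes remained for the strains, 222 and 161 for the F1 minus C57BL/6J and 129S1/SvImJ, and 32 for mid-parent. Without background subtraction the crosses gave 2 and mid-parent 15. The crosses gave 2 with the processed signals, 2 with the deposited ratios, 1 with Cy5 alone, 2 with array weights and 1 with only the arrays compared, where the strains gave 633. Array weights gave 1004 for F1 minus C57BL/6J, and a trended robust fit 38 for mid-parent. With the letter as a random block F1 minus C57BL/6J gave 210, mid-parent 29 and any difference 433. With a mean per letter, which leaves 10 values, the strains gave 318, the crosses 1, F1 minus C57BL/6J 12, F1 minus 129S1/SvImJ 68, mid-parent 0 and any difference 126, and the male list against mid-parent 0.29 (adjusted p = 0.060). With slide as a block the F1 gave 258 against C57BL/6J, 126 against 129S1/SvImJ and 9 against mid-parent, and with scan day 251, 145 and 20. Without slide 5 these were 142, 116 and 2. Slides 2 to 4 alone gave 305 for the strains, 52, 38 and 0 for the F1 comparisons and 128 for any difference. With an estimated correlation the lists kept their medians but not their calls for male genes between the crosses (0.34, adjusted p = 0.28; range over alternatives 8.6e-07 to 0.43), female genes between the crosses (-0.30, adjusted p = 0.083; 2.8e-05 to 0.38) and male genes against mid-parent (0.41, adjusted p = 0.33; 3.5e-07 to 0.33), and with fry the adjusted p were 0.43, 0.38 and 0.11.

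Leaving out each array in turn gave 805 to 1073 genes for the strains, 0 for the crosses throughout, 221 to 396 for F1 minus C57BL/6J (221 without H2, 233 without H3), 175 to 418 for F1 minus 129S1/SvImJ (175 without G3, 211 without A3), 27 to 81 for mid-parent (27 without M6, 31 without H3, 32 without C4 or H2, 39 without G3) and 478 to 742 for any difference. List medians ran from 0.41 to 0.68 (female) and 0.21 to 0.41 (WNT) between the strains, 0.31 to 0.41 (male) and -0.40 to -0.20 (female) between the crosses, and 0.31 to 0.49 (male) and 0.35 to 0.49 (germ cell) against mid-parent. The median position ran from -0.067 to 0.080 and its slope from -0.050 to 0.031.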

Other observations

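The test of X-linked genes and that of the shared sign of neighbours were chosen only after the result was seen, and the tests of adjacent pairs and of the trophoblast genes not seen before were chosen before it. Called genes lay next to each other along the chromosomes more often than chance. Of 18090 tested genes with a place in the gene table of GRCm38.p6, 786 differed between the strains, and 80 adjacent pairs were both called, against a mean of 35.5 and at most 60 in 10000 shuffles (permutation p = 1e-04, the smallest they can give). In 56 of the 80 pairs both genes had the same sign, against 43 by chance (permutation p = 0.0021). Gbp2b, Gbp2 and Kyat3 stood in a run, all lower in C57BL/6J, while Trim6, Trim34a and Trim12a were all higher. These runs were chosen after their values were seen. With 80 such pairs the data are in line with the idea that called genes lie in blocks along the chromosomes, and shared probes or related sequences among neighbours were not tested.

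If each X-linked strain difference followed the maternal X of the cross, all would take the same relation in the reciprocal comparison. Of 13 X-linked genes called between the strains 9 had the opposite sign there and 4 the same, where 442 of 773 autosomal genes (57.2%) also had the opposite sign. Of the 3 with a reciprocal p under 0.01, 2 had the opposite sign. None of the 3 was called between the crosses, so these data cannot decide whether every X-linked gene follows a shared rule. The 2 of opposite sign were Mbnl3, a splicing regulator (0.45 between the strains and -0.48 between the crosses), and Rps6ka3, a kinase of the MAPK pathway (0.65 and -0.47). The other was Lancl3, at -1.97 ± 0.34 between the strains and -2.00 ± 0.34 between the crosses (adjusted p = 0.18), with means of 0.33 ± 0.26 (SD) in C57BL/6J, 2.30 ± 1.06 in 129S1/SvImJ, 0.47 ± 0.12 in (B6x129S1)F1 and 2.47 ± 0.37 in (129S1xB6)F1. In Lancl3 each cross lay at the level of the strain named before the x in its name. The genes were chosen after their values were seen, and none was called between the crosses, although Lancl3 gained a call in 7 of 15 alternatives (adjusted p from 5.6e-04 to 1.0).

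By p rather than by size, genes of the placental trophoblast were among the leading differences between the crosses. Tpbpa, a trophoblast-specific protein, showed 0.86 ± 0.22 (means 1.03 ± 0.48 (SD) in (B6x129S1)F1 and 0.16 ± 0.16 in (129S1xB6)F1), with Prl2b1, a placental prolactin, at 0.51 ± 0.12 and Tpbpb at 0.46 ± 0.11, none of them called. A list of trophoblast genes was written after these were seen. Its 11 other tested members had a median of 0.10 in the same direction, with 9 above 0 (camera p = 0.0084, and p = 0.052 with an estimated correlation). All 17 had a median of 0.18. Traces of placental RNA in some samples may explain this, given the median of 0.10. The same 11 genes had medians of 0.10 between the strains and 0.04 against mid-parent.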
